A study of Mus musculus with 192 samples.

How the data were processed

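Single cells of clonal sublines of the mouse melanoma line B2905 were sequenced with Smart-seq2, a full-length method without molecular identifiers. The titles name the subline and cell of each of the 192 samples, and these names gave 24 groups of 8 cells. For 1 cell of C24 the source name gives only the line, and its title was used. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.5, aligned with STAR 2.7.3a, processed with Picard 2.22.3 and GATK, and quantified with RSEM 1.3.2 on the GRCm38 (mm10) mouse genome; the GATK version and the annotation release are not given in the sources used here. The authors deposited RSEM's expected count per gene and cell, in which reads that fit several genes are split between them and which need not be whole. The authors also deposited TPM per gene and cell, which divides by gene length and sums to a fixed total in each cell. A deposited FPKM table was not used. The deposited list of expressed mutations gives a site, a gene and a coding change in each line and names no cell.

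The tables held 55401 genes, and 54349 of their identifiers, with their version numbers, matched the gene name table and the GENCODE vM21 annotation of GRCm38, from which symbols and positions were taken. Of the expected counts above 0, 7.22% were not whole, and they were rounded to whole numbers. No pair of cells held identical values. A cell was kept with at least 50000 counts and at least 1000 genes with a count, which left out 4 cells, C3 cell 8, C4 cell 8, C5 cell 8 and C8 cell 6. Counts of the kept cells of a subline were summed, since a cell is not an independent replicate of its culture. The sums held 16348980 to 30770656 counts, and a gene at 0 in a sum could have had up to 3 counts, which amounts to 0.095 CPM in C22 and 0.198 CPM in C8. A gene was tested when it had a count in at least 20 cells and at least 5 CPM in at least 6 sublines, which left 10602 genes. Levels are given as CPM of the sums over tested genes with TMM scaling, and logarithms as log2(CPM + 1), which understates differences of low genes. Chromosome medians and the levels of imprinted and Y-linked genes were first computed on plain totals and then put on this same scale, after their values had been seen.

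The relation of genes to the melanocytic score was fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with the plate as a term, over 23 sublines. C23 was left out because all its cells carry a plate name that no other whole subline has. The members of the score's own list were left out of the count. Plates were compared with the same test over 12 and 11 sublines. Benjamini-Hochberg adjusted p-values under 0.05 were called. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. Shares of cells carry exact binomial (Clopper-Pearson) intervals at 95%. Relations between list scores were tested with Pearson's r and Spearman's rho and 100000 two-sided permutations each, adjusted over 136 pairs, with genes on both lists of a pair left out. Split-half r is the correlation over sublines of the odd-numbered with the even-numbered cells. The sublines, 17 expression lists, a list of 51 driver genes and the marker genes of other cell types were set before examining the data. So were the filters, the rule for named genes and these tests, except fry. The random lists against which the SDs of these lists are set were not part of that plan either. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the remaining steps.

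Genes were named by this rule: the 20 genes of largest SD with a mean of at least 50 CPM, up to 10 genes of smallest p in each direction among called genes, up to 4 members of largest SD of each list or the members that passed, and 14 genes always. Some genes that this rule takes are not reported here. Other named genes were chosen after their values were seen, which holds for Gfra2 as a slope, Ptprz1 as a slope, Ube2c, Cdk1, Birc5, Rps12, H2-D1, Tapbp, Kmt2d, the further pigmentation genes and the Y-linked genes. On data simulated from the real sums with 200 changed genes among 10602, the test of the melanocytic slope recovered 59% of genes with a slope of 1 and 14% of those with a slope of 0.5, and 3 of its 76 calls were unchanged genes. The test between plates recovered 55% of genes with a log2 difference of 2 and 18% of those with a difference of 1, and 1 of its 74 calls was an unchanged gene.

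Alternatives tried were DESeq2 1.42.0 with its size factors, those size factors in edgeR, no gene filter beyond a total of 10 counts, limma on log2 of the mean TPM with a pseudocount of 1 or 0.1, only cells of P01 and P02, a stricter cell filter of 200000 counts and 2000 genes, odd-numbered or even-numbered cells, each subline left out, no plate term, and the sublines of each plate alone. Fits without the 2 C8 cells of the plate name Sub, and fits with the score and the genes from different cells, were added after seeing the data, as were nearest neighbours within each plate. The relation of genes to the interferon score, the list tests between plates, and every test of Y-linked genes, of imprinted genes and of chromosomes were also added after seeing the data. Relations of expression with mutations, which had been planned as a genetic distance between sublines, 2 mutation axes and mutations per subline, were not run, because the mutation list names no cell.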

Results

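Single melanoma cells of the mouse line B2905, which the labels place in an HGF-transgenic C57BL6 background, were profiled by full-length RNA sequencing (Smart-seq2). The cells came from 24 clonal sublines, each grown from the parental line, with 8 cells per subline and 192 cells in all. No treatment was named, so the data address how far sublines of a single tumour line differ in expression. The only batch that the titles give is the plate, with 92 cells on plate P01, 88 on plate P02 and 12 under the plate name Sub. Sublines C1 to C12 were on P01 and sublines C13 to C22 and C24 on P02, so plate and subline cannot be told apart. Each subline of P01 and P02 also filled a plate column of its own, so column and subline cannot be told apart either. All 8 cells of C23 and 4 cells of C3, C4 and C8 carried the name Sub, whose meaning the labels do not give.

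A cell was kept when it held at least 50000 counts and at least 1000 genes, which left 188 cells. Their totals ran from 890670 to 4901389 counts with a median of 3421440, and the median cell had a count for 8136.5 genes. The counts of the cells of a subline were added up, and the 24 sums held 16348980 to 30770656 counts. A subline was the unit of every test with a p-value, so p-values measure only the spread between these sublines. That spread may in part be technical, since the labels name no repeat culture of any subline. The tests took sublines as independent, but all came from the same parental line. The labels do not give how sublines are related, and shared descent could make the p-values too small. Intervals and upper limits given for counts cover counting error only, because reads copied by PCR without molecular identifiers are not independent molecules.

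Sox10 was counted in all 24 sublines and Mitf in 22, while most pigmentation genes were rare or not counted. Sox10, a transcription factor of the neural crest and melanocyte lineage, was detected in 181 of 188 cells and spanned 74.9 CPM in C6 to 296 CPM in C15, with an SD of 0.47 on the log2 scale (n = 24 sublines). Axl, a receptor tyrosine kinase of dedifferentiated melanoma cells, was detected in 187 cells and spanned 316 CPM in C4 to 1830.0 CPM in C16. Gpnmb, a melanosome glycoprotein, spanned 245 CPM in C5 to 3721 CPM in C22. By contrast, Tyr, which encodes the rate-limiting enzyme of melanin synthesis, had no count in 188 cells, which allows a share of up to 1.94% of cells with a count if cells are taken as independent, and Slc45a2, Oca2, Gpr143 and Ednrb had none either. Pmel was counted in 10 cells, Mlana in 11, Dct in 33 and Tyrp1 in 2, and Mitf, the master regulator of melanocytes, reached a median of 8.39 CPM and at most 31.3 CPM, in C4. Only 8 of the 20 pigmentation genes passed the expression filter.

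Further melanoma genes were named in advance whatever their values. Met, the receptor for HGF, spanned 97.5 to 323 CPM (SD 0.44 on the log2 scale), and Hgf itself was counted in 21 cells with a highest level of 12.9 CPM, in C9. Trp53, which encodes p53, spanned 83.4 CPM in C10 to 386 CPM in C4. Cdkn2a, a cell cycle inhibitor locus, had no count in any of 188 cells, with the same upper limit of 1.94% of cells with a count. Ngfr, a neurotrophin receptor of neural crest cells, spanned 0 CPM in C13 to 860 CPM in C16 with an SD of 2.39, and its values in the odd-numbered and even-numbered cells correlated with r = 0.627 across sublines. Cd274, which encodes the immune checkpoint ligand PD-L1, was counted in 40 cells and spanned 0 to 34.5 CPM. Other cells of a subline did not repeat the values of Met, Cd274 and Hgf, with split-half r of -0.175, -0.012 and 0.007. B2m, the light chain of MHC class I, spanned 312 CPM in C18 to 7912 CPM in C8, and without the 2 C8 cells of the different plate name, each with under 2000 genes, the C8 level was 2944 CPM.

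Markers of other cell types were near the limit of detection. Dcn and Lum of fibroblasts, Cd3e, Cd14, Tyrobp and Cd52 of immune cells, Kdr and Cldn5 of endothelium, Krt1, Krt10, Krt15 and Epcam of epithelium, and the globin genes Hba-a2, Hbb-bs and Hbb-bt had no count in 188 cells. Ptprc was counted in 2 cells and Col3a1 in 15. Lyz2, a lysozyme of myeloid cells, was the most widely detected of these markers, with counts in 35 cells of 15 sublines and a highest level of 82.2 CPM, in C13.

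The question of which genes set the sublines apart was answered with the SD of log2(CPM + 1) across the 24 sublines. Acta2, the smooth muscle actin of contractile cells, had the largest SD among the genes with a mean of at least 50 CPM, 3.95 on the log2 scale, and spanned 0 CPM in 7 sublines to 1299 CPM in C21, with a median of 58.4% of a subline's counts in a single cell. Myl9, a myosin light chain of contractile cells, spanned 0 CPM in 4 sublines to 439 CPM in C3. Pmp2, a lipid-binding protein of myelin, spanned 0.222 CPM in C17 to 1225 CPM in C1, and Moxd1, a monooxygenase homologue, spanned 0 CPM in 3 sublines to 379.6 CPM in C8. Fgf13, an intracellular fibroblast growth factor homologue, spanned 0 CPM in 2 sublines to 233 CPM in C21. Mmp1a, an interstitial collagenase, reached 770.05 CPM in C16 against a median of 11.0 CPM, and a single cell held a median of 73.8% of the counts of a subline.

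Usp18, Oasl2, Ifit1 and Ifit3, 4 of these 20 genes, were on the interferon response list fixed in advance, and Cmpk2, Oas2, Ifit3b, Trim30a and Cxcl10 are known to be induced by interferon. Usp18, which restrains interferon signalling, spanned 0 CPM in C4 to 1016 CPM in C3. Ifit1, an antiviral RNA-binding protein, spanned 0 CPM in C6 to 821 CPM in C11, with a median of 60.3% of a subline's counts in a single cell. Oasl2 spanned 0 CPM in C6 to 352 CPM in C5, Oas2 0 CPM in C4 to 215 CPM in C7 and Cmpk2 0 CPM in C4 to 370.2 CPM in C22. Ifit3 spanned 2.77 CPM in C4 to 1990.3 CPM in C22 and its close copy Ifit3b 0 CPM in C4 to 593 CPM in C22. Trim30a, of a tripartite-motif family, was at 0 in 10 sublines and reached 226 CPM in C7. Cxcl10, a chemokine that attracts T cells, reached 805 CPM in C3, but a single cell held a median of 95% of a subline's counts and the split-half r was -0.445, so its subline values rested on single cells.

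Peg10, Sgce and Mest, imprinted genes that are expressed from the paternal copy on chromosome 6, had SDs of 2.76, 2.54 and 2.87 on the log2 scale. Sgce, at positions 4674350 to 4747207 of chromosome 6 in GRCm38, spanned 0.651 CPM in C7 to 498 CPM in C3 and had the highest split-half r of the 20 genes, 0.962. Peg10, the neighbouring gene at 4747306 to 4760517, spanned 0 CPM in 4 sublines to 297 CPM in C1, and Mest, at 30723547 to 30748465, spanned 0 CPM in 3 sublines to 661 CPM in C12. Magea8, a cancer-testis antigen gene on the X chromosome, was at 0 in 8 sublines and reached 199.7 CPM in C15. Prl2c3, a prolactin family gene on chromosome 13, was counted in 26 cells, was at 0 in 15 sublines and reached 2474 CPM in C16, and a single cell held a median of 70.8% of a subline's counts. The values of Prl2c3, Magea8, Trim30a, Ifit3 and Ifit3b are uncertain, because each has near-identical copies among which the authors' counting could split reads.

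**Figure D1:**
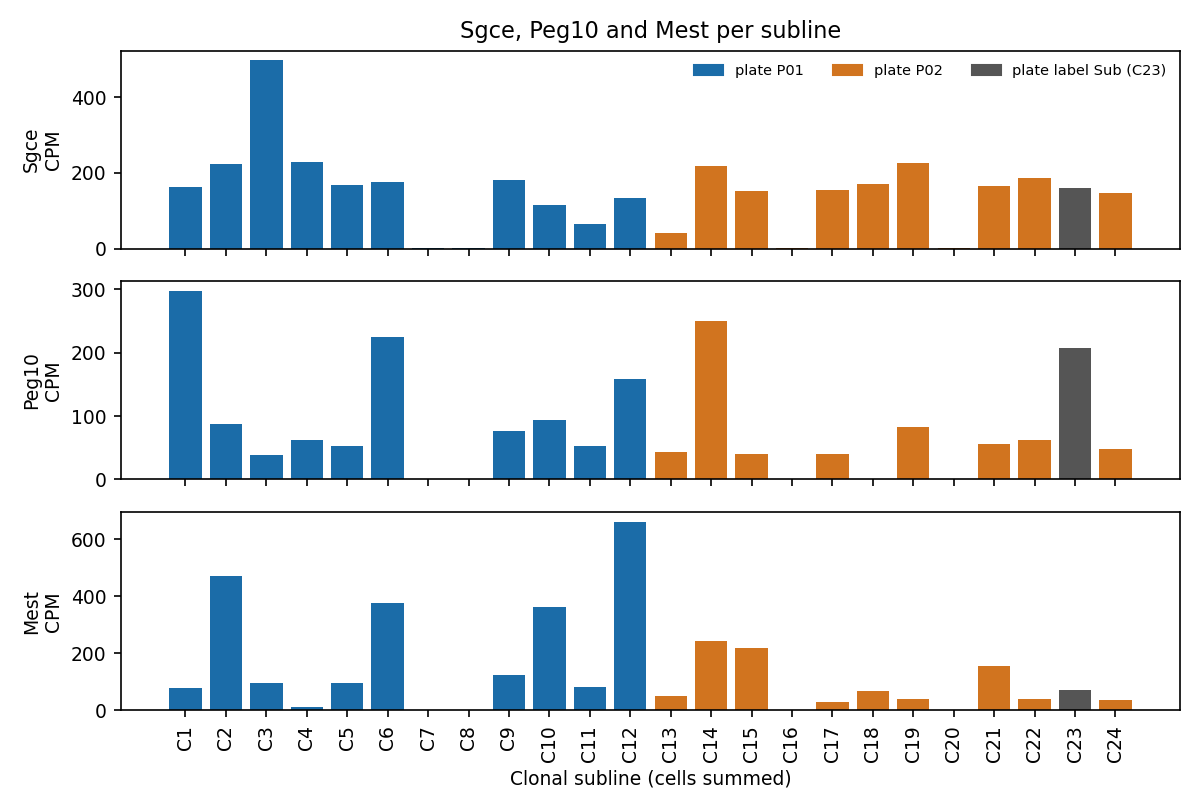
Bars give the CPM of Sgce, Peg10 and Mest (rows) in the summed cells of each of 24 sublines (x axis), coloured by plate, without replicates and so without error bars. In C7, C8, C16 and C20 all 3 genes lie under 2 CPM, and in the remaining sublines Sgce lies between 42.2 and 498 CPM.

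**Figure D2:**
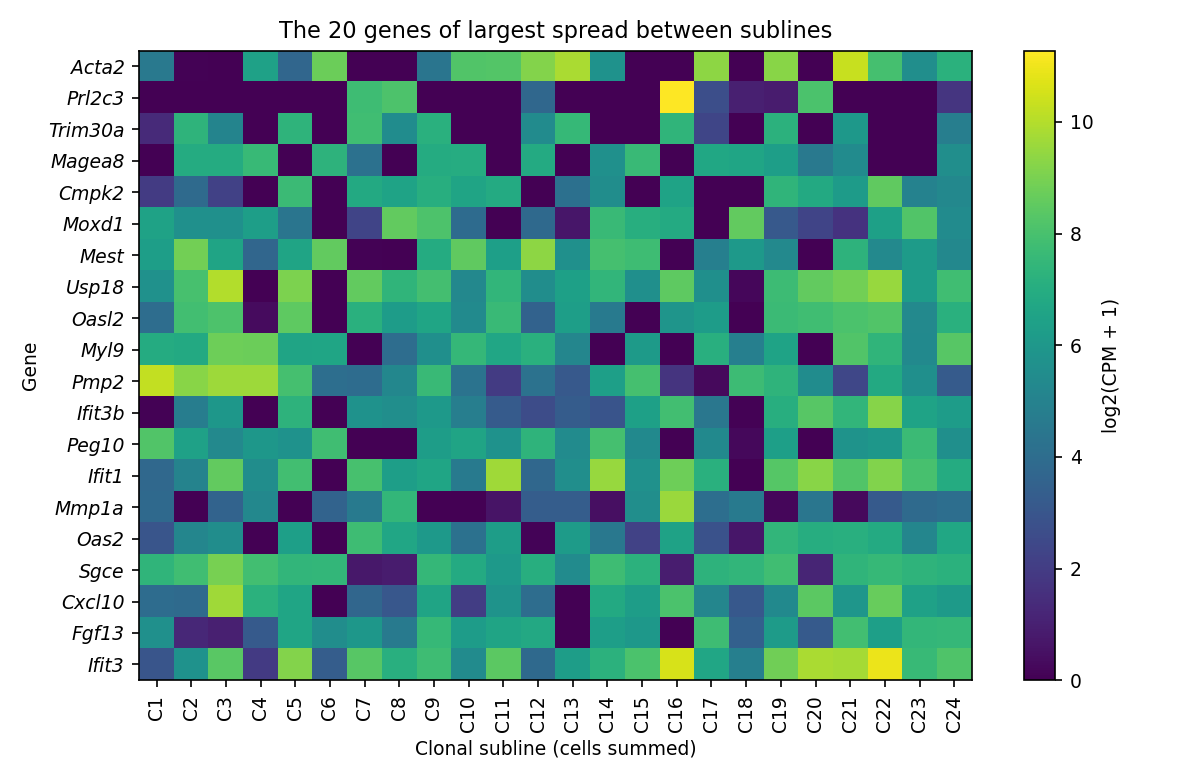
Heat map of log2(CPM + 1) for the 20 genes of largest SD (rows, sorted by SD) in the summed cells of each of 24 sublines (columns). Acta2 in the top row has the largest SD, 3.95, from 0 CPM in 7 sublines to 1299 CPM in C21.

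No test applied to the spread of a single gene, because each subline gave a single sum. The median gene past the expression filter had an SD of 0.948 on the log2 scale and a split-half r of 0.223, and the 4209 genes with at least 50 CPM had a median SD of 0.657, which is 1.58-fold. The 20 genes had a median split-half r of 0.73, against 0.363 for the genes with at least 50 CPM from which they were drawn. They were picked for a large SD on the sums of the same cells, which can raise this r.

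The spread of 17 gene lists fixed before the data were examined was then set against random lists matched on mean expression. Genes of a random list were drawn independently of each other, whereas members of a fixed list can move together. A percentile near 100 is therefore a description and overstates how unusual a list is. The interferon response list had the largest median SD, 1.68 on the log2 scale, at percentile 100 of the random lists, and 23 of its 25 measured members had an SD over 1. Its score, the mean z-score of the members, was highest in C22 and lowest in C4, and its scores in the odd-numbered and even-numbered cells correlated with r = 0.815. Immune ligands and cytokines followed with a median SD of 1.65 at percentile 100 but a split-half r of 0.363, in which Spp1, which encodes osteopontin, spanned 0 CPM in C17 to 1885 CPM in C13, and Cxcl12, a chemokine, spanned 0 CPM in C16 to 1197 CPM in C10. Ccl5, another chemokine of that list, reached 142.5 CPM in C15. MHC class I antigen presentation had a median SD of 1.28 at percentile 99.97 and a split-half r of 0.598, in which Psmb8, a subunit of the immunoproteasome, spanned 0.0741 CPM in C17 to 195 CPM in C5 and H2-T23, a non-classical class I gene, 0 CPM in C4 to 216 CPM in C3. Psmb9 reached 32.0 CPM in C5 and Nlrc5, a transactivator of class I genes, 25.3 CPM in C2.

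Lists of melanoma cell states came next. The dedifferentiated and invasive list had a median SD of 1.17 at percentile 99.68 but a split-half r of 0.258, in which Ccn2, a target of the Hippo pathway, reached 180.4 CPM in C8 and Nt5e, an ectonucleotidase, 92.8 CPM in C18. The neural crest-like list had a median SD of 1.11 at percentile 99.7 and a split-half r of 0.451, in which Ptprz1, a receptor phosphatase, reached 95.0 CPM in C21 and Gfra1, a co-receptor for GDNF, 241 CPM in C15. Extracellular matrix and mesenchymal genes had a lower median SD of 0.76 at percentile 99.18, although Timp3, a metalloproteinase inhibitor, spanned 0 CPM in C8 to 1994 CPM in C13 and Postn, a matrix protein, 0.0714 CPM in C20 to 298 CPM in C2. The 8 measured melanocytic genes had a median SD of 0.872 at percentile 58.54, with Rab38, a melanosome trafficking protein, reaching 65.1 CPM in C3 and Mc1r, the melanocortin receptor, 82.0 CPM in C22.

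Stress, growth and metabolic lists had median SDs of 0.496 to 1.07, with split-half r of 0.361 for p53 targets to 0.613 for MAPK pathway output. Within the unfolded protein and amino acid stress list (median SD 0.877, percentile 99.4), subline C18 had the highest score and the highest levels of Atf3 at 258 CPM, Trib3 at 494 CPM and the cystine transporter gene Slc7a11 at 147 CPM. Within cholesterol synthesis (0.877, percentile 99.85) the score was highest in C14, where Hmgcs1, an early enzyme of the pathway, reached 453 CPM, and lowest in C11. Among p53 targets (0.975, percentile 92.6), Phlda3, an inhibitor of Akt, spanned 12.5 CPM in C4 to 446 CPM in C5 and Sesn1 reached 172 CPM in C22. Hypoxia and glycolysis genes had a median SD of 0.648 at percentile 75.84, in which Ndrg1 reached 191 CPM in C2 and Pdk1, which keeps pyruvate out of mitochondria, 175 CPM in C23. Among MAPK pathway output genes (0.838, percentile 47.27), Phlda1 spanned 0.272 CPM in C3 to 80.8 CPM in C11, and among handling stress and immediate early genes (1.07, percentile 87.95) Dusp1 spanned 0.0382 CPM in C1 to 208 CPM in C19. Oxidative phosphorylation genes had the smallest median SD, 0.496 at percentile 0.36, with Uqcrfs1, a subunit of complex III, spanning 12.8 CPM in C3 to 246 CPM in C20.

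Cell cycle lists differed between sublines, but other cells of the same subline did not repeat the values. The mitotic genes of the G2/M list had a median SD of 0.992 at percentile 100, and Cenpf, Cdc20, Kif11 and Kif20a were all lowest in C16, at 0, 0, 0 and 3.38 CPM. C16 also had the lowest median number of genes per cell of the 24 sublines, 5978. The split-half r of the G2/M list was only 0.039, and that of the G1/S list, with a median SD of 0.852 at percentile 99.36 and Chaf1b spanning 0 CPM in C15 to 256 CPM in C21, was -0.034. Wnt pathway targets, with 4 of 14 members measured, had a median SD of 0.97 at percentile 30.95 and a split-half r of -0.11, and Lef1 reached 24.5 CPM in C21.

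**Figure D3:**
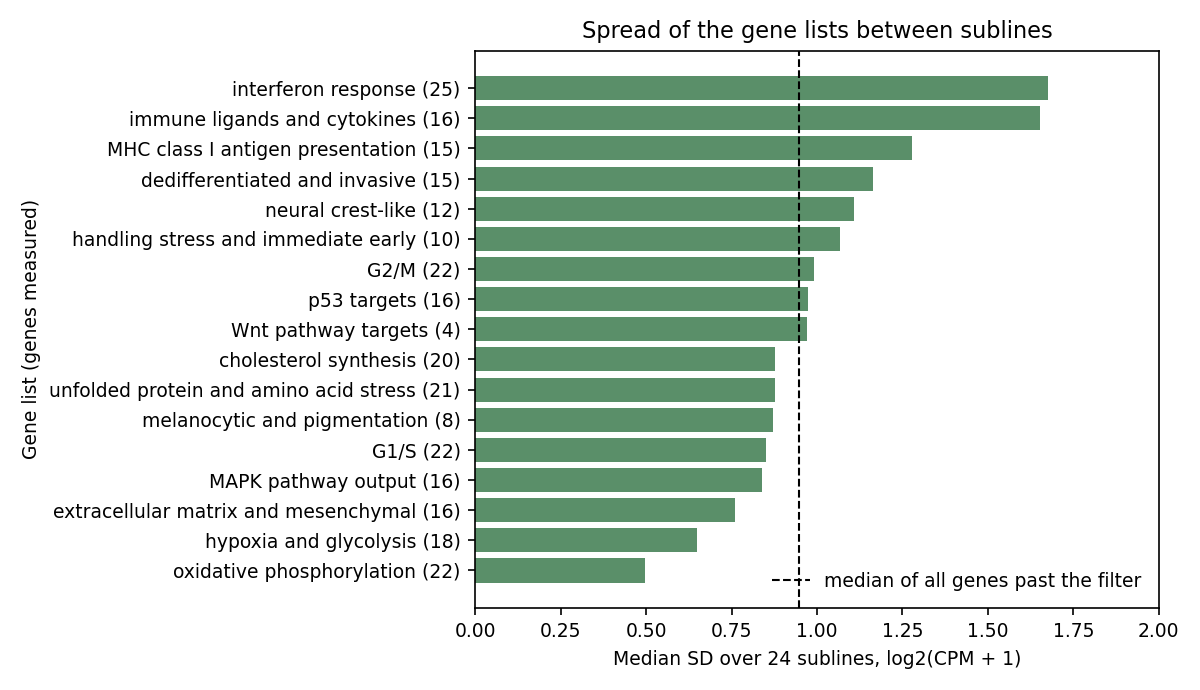
Bars give the median SD of log2(CPM + 1) across 24 sublines for each of 17 gene lists, with the number of measured genes in brackets, and the dashed line gives the median of all genes past the expression filter, 0.948. The interferon response list lies highest at 1.68 and the oxidative phosphorylation list lowest at 0.496.

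Which programmes rose and fell together over sublines was tested on all 136 pairs of list scores. The MHC class I score followed the interferon score. Subline C4 had the lowest score of both lists and no count of Usp18, Cmpk2, Oas2, H2-T23, Psmb9 or Nlrc5 in the sum of its cells. Not all interferon-induced genes were absent there, with Ifit1 at 44.7 CPM and Cxcl10 at 147 CPM. These levels may rest on few cells, since a single cell held a median of 60.3% and 95% of a subline's counts of Ifit1 and Cxcl10. C22 had the highest interferon score and C5 the highest MHC class I score. Pearson's r between both scores was 0.806 (n = 24 sublines, permutation p = 1e-05, the smallest these permutations can give, Benjamini-Hochberg adjusted p = 0.00136 over 136 pairs), and Spearman's rho was 0.79 (permutation p = 2e-05, adjusted p = 0.00272). Within the plates r was 0.922 over the 12 sublines of P01 and 0.611 over the 11 sublines of P02, and without C4 and C6, the sublines farthest from the median of either score, it was 0.693. Over the P02 sublines alone, with the scores rescaled within them, r was 0.683 and the adjusted p was 0.65. It was the only pair past the adjusted threshold, and 21 pairs had an unadjusted p under 0.05. The scores of no list fell into separate clusters.

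**Figure D4:**
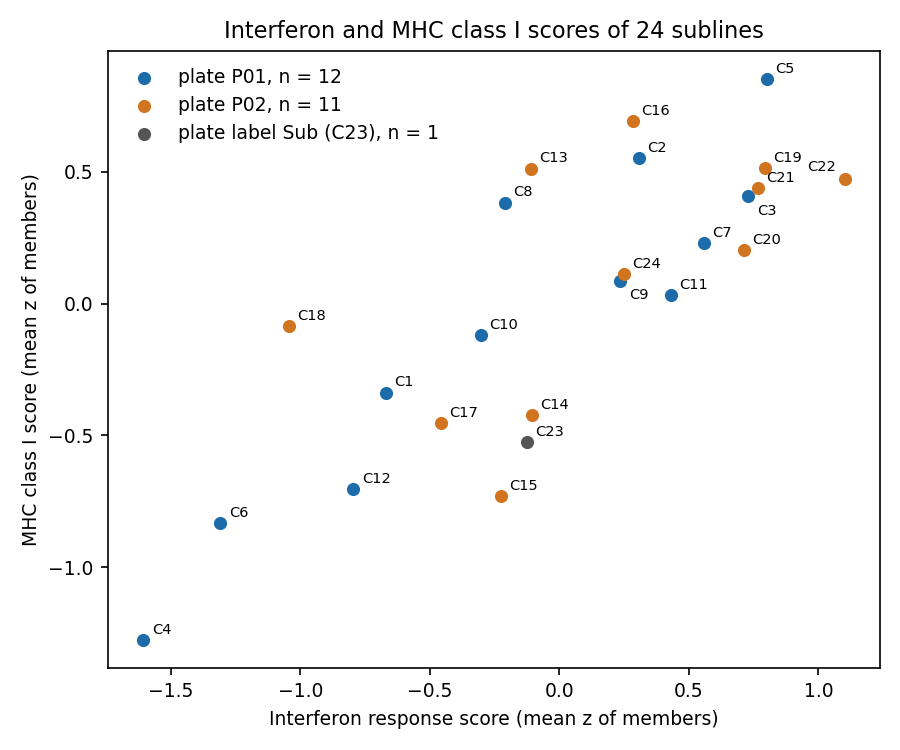
Score of the MHC class I list against that of the interferon response list, a point per subline (n = 24), coloured by plate. Sublines high in the interferon score are high in the MHC class I score, with r = 0.806, and C4 lies lowest on both axes.

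Whether expression followed the melanocytic state was tested as a slope per 1 SD of the melanocytic score over 23 sublines, with the plate held constant. None of the 16 other lists and none of the genes named in advance passed. Among the neural crest-like genes 2 of 12 had a positive slope, with Gfra2 at -2.31 ± 0.83 and Ptprz1 at -2.87 ± 1.25 (log2 per SD of the score, SE, n = 23 sublines). Hgf had a slope of -4.11 ± 1.23 at levels of at most 12.9 CPM, Axl of -0.20 ± 0.12 and Ngfr of -0.50 ± 0.46. By edgeR's quasi-likelihood test, 0 of 10594 genes passed an adjusted p of 0.05, with a smallest adjusted p of 0.605 and 476 genes at an unadjusted p under 0.05. DESeq2 called 32 genes, 3 with a positive and 29 with a negative slope, edgeR without the gene filter called 147, and limma called 0. Of the 16 other lists, 0 passed camera (lowest adjusted p = 0.12, and lowest adjusted p = 0.728 with an estimated correlation), and 0 members passed when adjusted over the list alone. The immune ligand list had a median below 0 with a mean and a test direction above 0, and the cholesterol synthesis list a median and mean below 0 with a test direction above 0.

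Genes were compared between the plates as a technical check, since each plate held different sublines. With camera and its preset correlation, the mitotic genes of the G2/M list were lower on P02 (adjusted p = 1.8e-07, and adjusted p = 0.425 with an estimated correlation). Of its 22 members 1 was higher there, and the log2 differences were -1.14 ± 0.37 for the ubiquitin-conjugating enzyme gene Ube2c, -1.15 ± 0.40 for the mitotic kinase gene Cdk1 and -0.99 ± 0.34 for Birc5, which encodes survivin (P02 minus P01, SE, 12 sublines of P01 and 11 of P02). The G1/S list (adjusted p = 0.00177, and adjusted p = 0.534 with an estimated correlation) and extracellular matrix genes (adjusted p = 0.0157, and adjusted p = 0.425 with an estimated correlation) were lower on P02 too. Higher on P02 were interferon response genes (adjusted p = 0.0157, and adjusted p = 0.798 with an estimated correlation), unfolded protein stress genes (adjusted p = 0.0157, and adjusted p = 0.425 with an estimated correlation) and handling stress genes (adjusted p = 0.0201, and adjusted p = 0.425 with an estimated correlation). Thus 6 of 17 lists passed with the preset correlation and 0 with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way, gave a lowest adjusted p of 0.198. The neural crest-like list had a median below 0 and a mean above 0, and the hypoxia list a median and mean above 0 and a test direction below 0, neither past the threshold.

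No single gene passed the test between plates. Rps12, a ribosomal protein gene, had the smallest p, with a log2 difference of -1.49 ± 0.26 and an adjusted p of 0.0515; all genes named in this comparison were chosen after their values were seen. By edgeR's quasi-likelihood test 0 of 10602 genes passed, with 970 at an unadjusted p under 0.05, and 4 list members passed when adjusted over the list alone. DESeq2 called 95 genes, 19 higher and 76 lower on P02, and limma on log2(TPM + 1) called 1. Without C7 the count was 2, and without C9, C10, C12 or C13 it was 1.

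The pooled list of expressed mutations named no cell, so it was described as a whole. It held 509622 distinct coding changes in 12254 genes, of which 299448, or 58.8%, were nonsynonymous substitutions and 134079, or 26.3%, were synonymous. Stop-gain changes numbered 15087, frameshift insertions 32732 and frameshift deletions 25564. Read along the coding strand, 46.9% of the 447567 substitutions were C to T or G to A, and T to C changes were 18.5% against 11.5% for A to G. Of 51 cancer driver and immune escape genes fixed in advance, 47 had at least 1 listed site, and the histone methyltransferase gene Kmt2d had the most, 494. Sites were not set against gene length, expression or the other genes of the list, so these counts do not single out driver genes. With no cell, genotype or quality beside a site here, neither a subline nor an inherited or sequencing origin could be assigned to any of them.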

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

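Of the tests weighed in this part, all were chosen after the result was seen, except the search for low levels among paternally expressed genes of other chromosomes and the reordering of the interferon score, whose results were unseen when their bounds were set.

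Within each subline, the lowest or highest of its 8 cells was set against the rest for total counts and for genes with a count, and in 11 of 48 such sets a cell stood apart, all at the low end, where chance gives about 1 in 20 sets, or 2.4. Total counts stood apart for C3 cell 8 at 136, C4 cell 8 at 14, C5 cell 8 at 16821, C17 cell 7 at 890670 and C18 cell 7 at 2471761. Numbers of genes stood apart for C1 cell 5 at 6385, C3 cell 8 at 12, C4 cell 8 at 6, C5 cell 8 at 3964, C9 cell 6 at 7359 and C11 cell 7 at 2164. The cells C3 cell 8, C4 cell 8 and C5 cell 8 had been left out of all results by the cell filter. They stood apart on both measures, so the sets are not independent and the 2.4 is only a guide. Several low cells in a subline can hide each other from this rule. It did not single out C8 cell 6, left out with 12 counts and 8 genes, or C8 cells 7 and 8, kept with 1788 and 1786 genes.

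The MHC class I and interferon scores moved together over sublines with r = 0.806. If a few cells set both scores, the score of one list in odd-numbered cells would not follow that of the other in even-numbered cells, but the lower of both such r was 0.478 (permutation p = 0.0178) and the other was 0.751 (permutation p = 4e-05). With the median number of genes per cell held constant r was 0.778, which argues against detection as the whole cause, and the lower of the r within P01 and P02 was 0.611, which argues against the plate. A shared interferon-driven programme that differs between sublines is a candidate explanation, as a hypothesis found and tested on the same data, and the labels give no treatment or exposure with which to test it.

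Ddx3y, Uty, Kdm5d and Eif2s3y, which sit on the Y chromosome, had no count in any of the 16 cells of C11 and C22, while their sum was 45.2 CPM (C3) to 570.6 CPM (C1) in the other 22 sublines, of which C19 had such a count in 2 of 8 cells, C8 in 5 of 7 and C21 in 5 of 8. Counting depth is argued against, since at the level of C3 the expected counts were 1002 in C11 and 1428 in C22 against 0 found, but expression in few cells, as in C19, stays open. Swapped cells stay open too, because the 0 cells of C11 and C22 with a count only restate the pattern. Cells of a female mouse would need a swap or a mix of lines, since all sublines were grown from the same parental line and 22 of them had Y-linked counts. Xist, the RNA of the inactive X chromosome, had 0 counts in these and all other sublines. That does not exclude such foreign cells, because a cultured line can lose its inactive X. Loss of the Y chromosome in these sublines may explain the pattern, and it was not tested on DNA.

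Peg10, Sgce and Mest, paternally expressed genes on chromosome 6, were together under 2 CPM in C7, C8, C16 and C20 of both plates, with Sgce at 0.65, 0.79, 0.84 and 1.21 CPM, and they also stood apart on genes of other chromosomes, with Prl2c3 at 217, 276, 2474 and 270.2 CPM against at most 12.7 CPM elsewhere and Acta2 at 0 as in 3 other sublines. Missed transcripts are argued against. At the lowest level elsewhere, 42.2 CPM, the expected Sgce count was at least 641 in each of these sublines against at most 34 found. A general loss of imprinted expression is argued against by 0 of 7 paternally expressed genes of other chromosomes under 2 CPM in all 4. Plagl1 came close to that bound, at 1.51 CPM in C7, 1.19 in C8, 2.25 in C16 and 1.96 in C20. Plagl1, Zrsr1 and Airn had medians of only 2.51, 2.83 and 4.69 CPM over sublines and inform little. Peg13 and Mcts2 lay at 2.46 CPM or more in each of the 4, and Kcnq1ot1 and Impact at 25.8 CPM or more. Loss of the paternal copy of chromosome 6 stays open and may explain the pattern. The medians of all 12 chromosome 6 segments in these sublines lay below 0, against 13 of 60 in the others. These 4 sublines may share descent, which was not tested, so their segments may not be separate cases. Nap1l5, a further paternally expressed gene of chromosome 6, could not decide it, because it reached at most 1.08 CPM in any subline. In segment 1, which holds the 3 genes, the medians were -0.31 in C7, -0.12 in C8, -0.40 in C16 and -0.34 in C20. All were smaller in size than the -1 of 1 copy in place of 2. C16 lay close to the -0.42 of 3 copies in place of 4, and past it in segment 2 at -0.47. Cells differed as well, with whole-chromosome medians of -0.18 in odd-numbered and -0.39 in even-numbered cells of C7. These medians therefore cannot tell loss from silencing of the 3 genes without loss of DNA, which is open too. In segment 1, C16, C20 and C7 had the lowest medians of all sublines, while C8 lay above C4, which had -0.15 there and Sgce at 229 CPM. In segments 2 and 3 a low median did not set the 4 sublines apart. There C19 had -0.21 and -0.13 (-0.05 in segment 1) and C15 had -0.34 and -0.32 (0.06 in segment 1), with Sgce at 226 and 152 CPM. C18, with the lowest whole-chromosome median of -0.33 and -0.08 in segment 1, had Peg10 at 0.17 CPM but Sgce at 171 CPM and Mest at 67.0 CPM.

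Between plates the real split gave 0 genes, so 100 of 100 splits of the 23 sublines gave as many by construction and say nothing about chance, and the highest other gave 1. For genes that follow the interferon score, 1 of 100 orders of the score within plates, the real one, gave as many as its 15 genes, and the highest other gave 0. This argues against a chance order, as far as 100 orders can show, for a score taken up after seeing the data. The reordering does not exclude noise shared by the score and the genes of the same cells. With score and genes from different cells the count was 0 in either direction, and without C4 and C6 it was 1.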

How the results depend on the processing

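Settings added after seeing the data were the fits without the 2 Sub cells of C8, the fits with scores and genes from different cells, and the list tests between plates. No paired analysis was possible because a cell number only names a cell and the cells of a subline were summed into 1 value. The planned fits along mutation axes, the genetic distance and the mutations per subline were not run, because the mutation list names no cell.

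For genes that follow the melanocytic score, edgeR called 0, DESeq2 32 and edgeR without the gene filter 147; all other settings gave 0, and leaving out each subline gave 0 to 0. Between plates, edgeR called 0, DESeq2 95, limma on TPM 1 and odd-numbered cells 1, and leaving out each subline gave 0 to 2. Of 17 lists between plates, 6 passed with the preset correlation, 0 with an estimated correlation and 0 with fry. Pairs of lists past the threshold numbered 1, against 2 with TPM, 2 with only P01 and P02 cells, 0 in P02 sublines alone, 3 with a pseudocount of 0.1 and 3 with unscaled values. The r of MHC class I with interferon ran from 0.683 to 0.901 over 12 settings and passed in 11, the exception being P02 sublines alone at 0.683, a set of 11 sublines. The cause of the other differences was not tested.

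Of 165 alternative SDs of genes and lists, 159 stayed within 1.5 times, and the other 6 were median SDs of lists in part of the cells: G1/S (0.852 against 1.85 in odd-numbered and 1.94 in even-numbered cells), G2/M (0.992 against 1.92 and 2.50), and in even-numbered cells MAPK output (0.838 against 1.40) and p53 targets (0.975 against 1.63). Of the 20 genes of largest SD, 17 were shared with TPM, 15 with odd-numbered cells and 14 with even-numbered cells. Depth limits what a level of 0 means, since up to 3 counts amount to 0.095 CPM in C22 and 0.198 CPM in C8.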

Other observations

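The relation of genes to the interferon score, the chromosome values and the nearest-neighbour values of this part were added after seeing the data.

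Genes outside the interferon list followed its score over 23 sublines with the plate held constant. H2-T22, a non-classical MHC class I gene, had a slope of 0.86 ± 0.12 (log2 per SD of the score, SE, edgeR adjusted p = 0.00108), Ifitm3, which blocks entry of viruses, of 0.87 ± 0.14 (adjusted p = 0.0072) and Ifi35 of 0.79 ± 0.13 (adjusted p = 0.00856). Parp14, an ADP-ribosyltransferase, had a slope of 2.52 ± 0.45 (adjusted p = 0.0147), and Oas2, a sensor of double-stranded RNA, of 2.86 ± 0.55 (adjusted p = 0.0169). Samd9l, Ifi204, Rnf213, Irgm1 and Ifi203 followed with slopes of 0.76 to 1.25 and adjusted p-values of at most 0.0169. H2-T22, Ifi203 and Ifi204 have near-identical copies, so their values are uncertain. In all, 15 genes passed with a positive slope and 0 with a negative slope among 10577 genes, with 333 at an unadjusted p under 0.05.

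Of the MHC class I list, 13 of 15 members had a positive slope on the interferon score, with H2-D1 at 0.87 ± 0.18, H2-K1 at 1.02 ± 0.23, the peptide-loading gene Tapbp at 0.54 ± 0.12, Psmb9 at 2.30 ± 0.69 and B2m at 0.51 ± 0.21. The list passed camera (adjusted p = 1.21e-14, and adjusted p = 0.00045 with an estimated correlation) and fry (adjusted p = 0.000286). These tests restate, on the same sums, the relation of both scores given above, so they add no separate evidence. None of its members passed over all genes, and 9 passed when adjusted over the list alone. Cd274 had a slope of 0.47 ± 0.52 and Axl of 0.03 ± 0.13, and neither passed. Median, mean and test differed in sign for the neural crest-like, dedifferentiated and Wnt lists, none of which passed.

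The count of 15 genes depended on single sublines and settings. It was 48 with DESeq2, 191 without the gene filter (87 positive, 104 negative), 38 with limma, 3 and 4 with odd-numbered and even-numbered cells, 23 without the plate term, 1 without C4 and C6, 0 with scores and genes from different cells in either direction, 5 without C4, 5 without C6, 7 without C22 and 9 without C18. All 370 alternative slopes of the 10 named genes were positive, and 306 had an adjusted p under 0.05. The 10 genes had been picked for positive slopes of small p. Of the 37 settings per gene, 23 left out a single subline, so the fits overlap and are not independent.

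Over 480 pairs of a subline and a chromosome, the median log2 level of a chromosome's genes, relative to each gene's median over sublines and to the subline's median over genes, lay past 0.3 either way in 20. Chromosome 16 had a median of 0.57 in C13 and -0.43 in C23, chromosome 13 of -0.49 and chromosome 14 of -0.44 in C19, and chromosome 12 of 0.44 in C20. Odd-numbered and even-numbered cells correlated with r = 0.64 over all 480 pairs, which are not independent.

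By rank correlation over the 2000 genes of largest SD between sublines, 109 of 188 cells (58.0%) were nearest to a cell of their own subline, against 3.66% by chance over all plates. These genes, of at least 30 CPM on average, were chosen on the sums of the same cells. The choice can raise the share, and no chance value given here allows for it. Among the cells of P01 alone the share was 63.3% against 7.42% by chance, and among those of P02 alone 64.8% against 8.05%, which does not separate subline from plate column. Over all plates it held for all 8 cells of C20 and of C23, whose plate name no other whole subline has, so that subline and batch cannot be told apart there, and for 0 of 8 cells of C11 and C17. Of the 8 cells of C7, 6 were nearest to a cell of C20 or C8.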
